A study of Mus musculus with 8 samples.

How the data were processed

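Dermal fibroblasts from 4 young mice (2 months old) and 4 old mice (18 months old) were profiled on Affymetrix mouse perfect-match arrays, 1 array per animal. Per the labels' protocols, skin was freed of subdermis and digested with collagenase, and cells lacking CD45, CD117, CD24, CD31 and EpCam but carrying Pdgfra and CD34 were sorted. Total RNA (6 ng) was amplified with a whole transcriptome kit for 18 cycles, and 8 micrograms of cDNA were fragmented and biotin-labelled. The submitters' processing notes name RMA and the R package affy, without versions. The deposited values are log2 probe set summaries. RMA corrects background, makes array distributions alike by quantile normalization and summarises the probes of a set by median polish. Quantile normalization hides a shift shared by most transcripts, and the summaries compress differences near background and near the top of the range. The table held 45141 probe sets with no missing value, rounded to 2 decimals. Array medians lay between 5.19 and 5.34, and the highest value was 13.04.

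Gene names came from the platform annotation given for the probe sets. It listed 1 symbol for 28898 probe sets, several for 551 and none for 15692, and the last 2 classes were not used for named genes. Of the 28898 probe sets, 28689 matched a gene ID in a RefSeq gene table of assembly GRCm38.p6, used only for names and synonyms, and 209 did not. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Each of 17097 genes was represented by its probe set of highest mean over the 8 arrays, and 7180 genes had more than 1.

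Old and young arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate), with Benjamini-Hochberg adjustment over all 17097 genes and a threshold of 0.05. Adjusted p-values of single genes come from this test. For 41 gene lists fixed before the data were examined, with at least 5 measured members each, camera was run with a preset inter-gene correlation of 0.01 and adjusted over lists. It was repeated with a correlation estimated per list, and with fry, whose p tests whether the members move, on balance, one way. The mean of each list's members per array, centred per gene, gave a list score, and its age difference was given an exact 2-sided permutation test. With 4 against 4 arrays the smallest p that test allows is 0.0286. The spread between animals was compared by the median over genes of the log2 ratio of SDs (each SD raised by 0.01, the rounding step), with an exact permutation test over 35 splits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

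Genes named in the text follow a rule fixed before the data were examined. It takes, in each direction, the 12 largest changes among genes past the threshold whose 4 old values all lie on one side of the 4 young values, leaving out predicted transcripts. It adds up to 4 called members of each thematic list with the largest change (or 2 of smallest p), all genes of the sort gate, and for each cell type or quality list the brightest member and the one of smallest p. Other genes are marked as chosen after their values were seen.

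The gene test was tested on simulated data for this comparison over 17097 genes, of which 200 were changed. It recovered 76% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1, and 3.81% of its calls were false. A simulated shifted list was called, and so was 1 of 41 unshifted lists. The simulated genes varied independently and held no background shift, so these rates do not cover correlated genes or a background that differs with age.

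The number of arrays limits the precision of all values, and no read depth applies. The series text says that 1 young and 1 old mouse were collected per day, but the labels do not tie the specimen number to the day, so no block was used. Alternatives covered a replicate block, centring or quantile normalizing again, leaving out dim genes, other ways of choosing probe sets, trend and robust settings, array weights, thresholds, other list tests and leaving out each array. A covariate for non-specific background, a restriction to bright list members and all alternatives for the 2 gene lists of the closing observations were added after seeing the data.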

Results

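Transcript levels were measured in sorted dermal fibroblasts of 4 young and 4 old mice, each animal on its own array, to ask how the fibroblast transcriptome differs with age. Values are normalized log2 levels. They correlated across the 17097 genes between 0.994 and 0.997 among young arrays, between 0.992 and 0.997 among old arrays, and between 0.983 and 0.990 across ages. The first principal component held 55.9% of the variance and separated the ages.

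The largest decreases in old fibroblasts were those of Rassf4, a Ras-association domain protein, and of Aldh1l2. Rassf4 fell from 8.56 ± 0.31 in young to 4.46 ± 0.17 in old (SD, n = 4 each), a log2 difference of -4.10 ± 0.15 (SE; 17.1-fold, adjusted p = 5.2e-07). Aldh1l2, a mitochondrial folate enzyme, fell by 3.71 on the log2 scale, and Bcat1, which starts the breakdown of branched-chain amino acids, fell by 3.15. Creb3l3, a membrane-bound transcription factor of the endoplasmic reticulum, differed by -3.60, Cgref1 by -3.23, the noradrenaline transporter Slc6a2 by -2.55 and the kinase Camk2a by -2.53. The non-coding transcript Mirg (-2.71), Flrt1 (-2.23) and Obox2 (-2.22) were also among the 12 largest decreases, as were the collagens Col14a1 and Col4a5. The call of Flrt1 was lost without old replicate 4 (adjusted p = 0.0505).

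Without a covariate, the largest increases were those of Cyp2g1, a cytochrome P450, and of Fabp4, a fatty acid carrier. Cyp2g1 rose from 5.77 ± 0.72 to 9.02 ± 0.70 (SD, n = 4 each), a log2 difference of 3.26 ± 0.40 (SE; 9.56-fold, adjusted p = 5.4e-04). With an index of non-specific background as a covariate, Cyp2g1 differed by 1.98 (adjusted p = 0.213). This was less than Fabp4 (3.61, adjusted p = 0.228), Csprs (2.91, 0.0534) or Akr1c14 (2.47, 0.338). All of them lost their calls with the covariate, as did Aqp1 (0.0531) and Fibin (0.256). The calls of Tcf24, Plscr4, Tmem176a, Ldhb, Igf2 and Tent5b were kept with it. Fabp4 rose by 3.02 ± 0.59 (SE), with young animals spread widely (SD 1.37). The water channel Aqp1 rose by 2.75, the growth factor Igf2 by 2.37 and the lactate dehydrogenase subunit Ldhb by 2.45. Csprs (2.94), Tcf24 (2.65), Plscr4 (2.60), Tmem176a (2.58), Fibin (2.52), Akr1c14 (2.42) and Tent5b (2.33) also rose, each with all old values above all young values.

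In all, 1688 genes were higher and 1310 lower in old fibroblasts among 17097 tested, 56.3% of the calls being higher. After a further quantile normalization the counts were 1415 and 1716, or 45.2% higher, so the balance of directions depended on scaling. At least 2-fold changes were found for 165 higher and 125 lower genes. The groups did not overlap for 3647 genes, 21.3% against 2.86% by chance. Non-specific probe sets rich in G and C bases also differed with age, by -0.61 in old. With that background index as a covariate 68 genes were higher and 99 lower. Of 122 called genes named here, 26 kept their call under that and the other alternatives run for single genes, thresholds not among them. The covariate made 25.7% of the called differences smaller by over 1.5 times. Among named genes these were Cyp2g1, Fibin (to 1.05), Col14a1 (-1.77), Mfap2 (-0.38), Eln (-0.14), Elovl6 (0.52), Fabp5 (0.53), Trarg1 (0.34), Cyp51 (0.31), Nfkbie (0.29), Cfb (0.57), Clu (0.56), Gpnmb (0.46), Mcm6 (0.28), Gpx3 (-0.44), Ddr2 (0.10), Sdha (0.12), Rpl19 (0.11), Usp2 (0.27), Errfi1 (0.14) and Sgk1 (0.16). It made those of Zfp521 (0.92), Ebf2 (0.78), Tfap2c (0.81), Tef (1.03), Krt5 (1.57) and Mal (1.05) larger by as much.

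**Figure D1:**
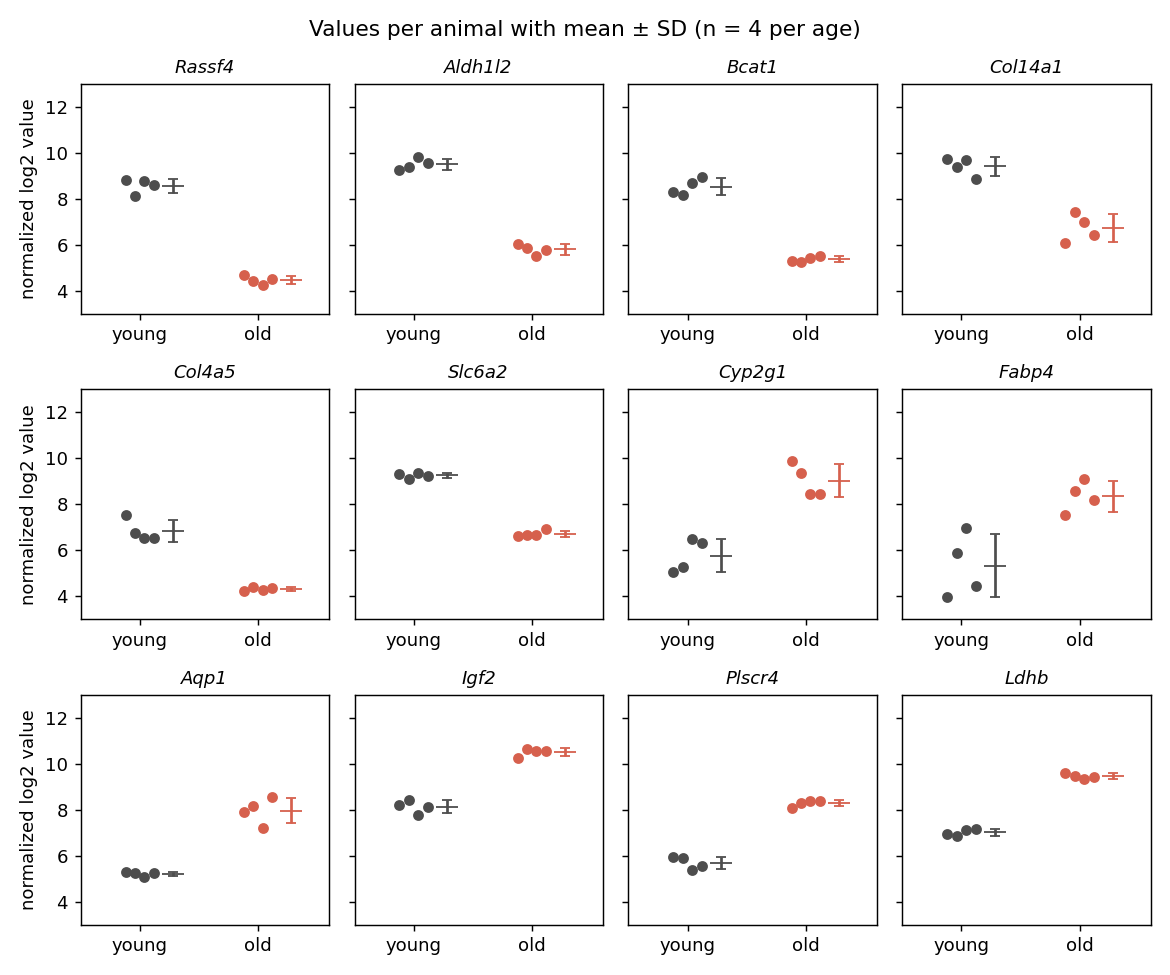
Normalized log2 values of 12 genes with large changes, 1 point per animal, with the mean ± SD of each age beside the points (n = 4). In each panel the 4 old values lie apart from the 4 young values, as Rassf4 falls from 8.56 to 4.46 and Cyp2g1 rises from 5.77 to 9.02.

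Collagen genes and the enzymes that mature collagen were lower in old fibroblasts. Of 23 measured fibrillar and network collagens, 14 fell, 1 rose and 8 did not pass (16 and 1 adjusted over the list alone). Col14a1, a fibril-associated collagen, fell by 2.69 on the log2 scale, and Col4a5, of basement membranes, fell by 2.51 to 4.31, a level that Y-linked genes also reached. Col5a3 fell by 1.02 and the anchoring fibril collagen Col7a1 was lowered 2-fold. The 1 that rose was Col12a1 (0.76), named after its value was seen. The list mean was -0.49 ± 0.03 (SE between arrays; camera adjusted p = 5.5e-08, adjusted p = 0.0243 with an estimated correlation). The main skin collagens Col1a1 (-0.19, adjusted p = 0.0652) and Col3a1 (-0.28, adjusted p = 0.00765), named after their values were seen, lay at 12.59 and 12.57 in young, near the top of the range where differences are compressed. The index of non-specific background was lower in old as well (-0.61).

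Of 24 collagen maturation genes, 16 fell and 8 did not pass (16 fell adjusted over the list alone). The lysyl hydroxylase Plod1 fell by 1.41, the prolyl hydroxylase subunit P4ha2 by 1.18, P3h1 by 0.88 and the cross-linking enzyme Lox by 0.85 on the log2 scale. The list mean was -0.43 ± 0.03 (SE, camera adjusted p = 1.1e-09), but adjusted p = 0.0705 with an estimated correlation. Among 38 genes of protein folding in the endoplasmic reticulum, 14 fell (16 adjusted over the list alone), among them Kdelr3 (-1.15), Creb3l1 (-0.86), Ssr2 (-0.77) and Sec31a (-0.54). That list mean was -0.23 ± 0.04 (SE, camera adjusted p = 7.1e-06, adjusted p = 0.413 with an estimated correlation).

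Of 13 proteoglycans (listed as small proteoglycans, although Hspg2 is a large one), 4 fell (5 adjusted over the list alone): Podn (-1.14), Hspg2 (-0.50), Aspn (-0.48) and Prelp (-0.36). The list mean was -0.23 ± 0.03 (SE, camera adjusted p = 0.00668, adjusted p = 0.206 with an estimated correlation). Matrix glycoproteins and elastic fibre genes moved both ways, 4 up and 6 down of 29 (5 and 6 adjusted over the list alone), and were not called as a list (adjusted p = 0.935). Mfap2 (-0.88), Fbn2 (-0.87), Matn2 (-0.73) and elastin, Eln (-0.58), were the largest changes. Of 25 matrix proteases and inhibitors, 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0826). The protease list was called lower with trend and robust settings (adjusted p = 0.0281) and with fry (0.00663), within a range over the alternatives to 0.413. Mmp16 fell by 1.28 and Mmp3 by 1.09, whereas the plasminogen activator Plat rose by 0.96 and Mmp11 by 0.76.

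Of 37 genes of lipid uptake, storage and synthesis, 12 rose in old fibroblasts and 25 did not pass (12 higher and 1 lower adjusted over the list alone). Fabp4 led, followed by the fatty acid elongase Elovl6 (2.83-fold), Apoc1 (log2 difference 1.35) and Fabp5 (1.24). The list mean was 0.33 ± 0.07 (SE, camera adjusted p = 0.00703, adjusted p = 0.592 with an estimated correlation). Of 19 cholesterol synthesis genes 8 rose (8 adjusted over the list alone), including Idi1 (1.24), Hsd17b7 (0.79), Cyp51 (0.67) and Stard4 (0.56), with a mean of 0.27 ± 0.08 (SE, camera adjusted p = 0.00703, adjusted p = 0.592 with an estimated correlation). With the background index as a covariate these lists had adjusted p = 0.0656 and adjusted p = 0.12, within ranges over the alternatives of 0.00159 to 0.592 and 8.2e-04 to 0.592. Among 18 regulators of adipogenesis 5 rose (5 higher and 1 lower adjusted over the list alone), including Klf5 (0.92), Zfp521 (0.52), Ebf2 (0.47) and Ppargc1b (0.34), and the list was not called (adjusted p = 0.208). Single arrays left out ended the calls of Elovl6 (young 4, old 1 or old 2; adjusted p up to 0.0597) and Klf5 (young 2, old 2 or old 4, up to 0.0568), and those of Ebf2 (6 arrays, up to 0.104), Ppargc1b (5 arrays, up to 0.113) and Zfp521 (7 arrays, up to 0.113). Keratinocyte markers moved the same way, with a list mean of 0.59 ± 0.33 (SE), but not in every array. Old replicate 1 scored 0.07 for lipid genes and -0.28 for keratinocyte markers, and young replicate 3 scored -0.05 and 0.31. The other arrays had scores of the same sign in both lists.

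Several groups of immune genes were higher in old fibroblasts. Of 40 interferon response genes, 16 rose and 3 fell (20 and 4 adjusted over the list alone), led by Samd9l (1.28), Ifit2 (0.92), Ifit1 (0.89) and Rsad2 (0.79). The list mean was 0.26 ± 0.05 (SE, camera adjusted p = 1.9e-04, adjusted p = 0.405 with an estimated correlation). Of 19 complement genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), including C2 (1.24), C4b (0.95), Cfb (0.92) and Clu (0.89), with a mean of 0.32 ± 0.04 (SE, camera adjusted p = 0.00361, adjusted p = 0.405 with an estimated correlation). Of 9 class 2 antigen presentation genes 3 rose (5 adjusted over the list alone), with H2-Ab1 at 1.15 and a list mean of 0.58 ± 0.13 (SE, camera adjusted p = 0.00395, adjusted p = 0.405 with an estimated correlation). The class 2 list was planned as a check for RNA of other cell types. Macrophage and dendritic markers were not called (camera adjusted p = 0.635). RNA of antigen-presenting cells and a change within fibroblasts were not told apart. The call of Clu was lost without any of 6 of the 8 arrays (adjusted p up to 0.0733). Keratinocyte markers (mean 0.59) moved the same way as these groups, but not in every array. Old replicate 1 scored -0.28 for keratinocyte markers, but 0.19 for complement and 0.18 for interferon genes. Young replicate 3 scored 0.31, but -0.11 and -0.05. The other arrays had scores of the same sign in these lists, with old replicate 4 highest for keratinocyte (0.93) and complement genes (0.23).

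Of 41 cytokines and chemokines 7 rose (7 adjusted over the list alone): Cxcl12 (0.78), Il15 (0.68), Cx3cl1 (0.62) and Il18 (0.60) led. Il15 rose from 4.18 in young, a level that Y-linked genes also reached, to 4.87 in old. The list had camera adjusted p = 0.0134, and adjusted p = 0.605 with an estimated correlation. Of 21 NF-kB targets and regulators 4 rose (4 adjusted over the list alone): Tnfaip2 (0.77), Tnfaip3 (0.70), Nfkbie (0.62) and Nfkbiz (0.27). That list had camera adjusted p = 9.9e-04 and adjusted p = 0.651 with an estimated correlation, and adjusted p = 0.0656 with the background index as a covariate (range over the alternatives 4.9e-05 to 0.651). By array scores, the exact permutation p was 0.0571 for cytokines and 0.143 for NF-kB genes. The NF-kB score was highest in old replicates 4 (0.42) and 2 (0.20), while old replicates 1 (-0.02) and 3 (0.00) lay at the level of young replicates 3 (0.01) and 4 (-0.01). Dissociation stress genes, of which 1 is also in the NF-kB list, had their highest scores in old replicates 4 (0.20) and 2 (0.06) too, and both lists had their lowest in young replicates 1 (-0.32 and -0.16) and 2 (-0.29 and -0.16). Without old replicate 4 the NF-kB mean was 0.22, against 0.31 with it. Class 1 antigen presentation was not called (2 up, 1 down of 18, 3 and 1 adjusted over the list alone, adjusted p = 0.241), although Nlrc5 rose by 0.88 and Psme1 by 0.34 while Pdia3 fell by 0.36. The calls of Tnfaip3 (4 arrays, adjusted p up to 0.0961), Nfkbiz (6 arrays, up to 0.114) and Pdia3 (4 arrays, up to 0.0564) were lost when single arrays were left out, and that of Cx3cl1 with the most variable probe set. Keratinocyte markers had a list mean of 0.59 as well.

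Of 25 genes of the TGF-beta response 6 rose and 1 fell (8 and 1 adjusted over the list alone). Ccn2, a matricellular growth factor, rose by 2.04 and Bambi, a decoy receptor of the pathway, by 0.87, with Skil at 0.68 and Tgfb2 at 0.57. Keratinocyte markers (mean 0.59) moved the same way, and old replicate 4 had the highest score of both lists (0.25 and 0.93). The scores had opposite signs in old replicate 1 (0.02 and -0.28) and in young replicates 3 (-0.14 and 0.31) and 4 (0.01 and -0.50). The list mean was 0.31 ± 0.08 (SE, camera adjusted p = 0.00989, adjusted p = 0.455 with an estimated correlation). Wnt genes moved both ways (6 up, 4 down of 39, or 9 and 4 adjusted over the list alone), with adjusted p = 0.935, a mean of 0.07 and a median of -0.04. Wnt5b rose by 1.14, Fzd7 by 0.65 and Tcf7l2 by 0.60, and Wnt11 fell by 0.67. The call of Tcf7l2 was lost with the most variable probe set (0.45, adjusted p = 0.0991; range over the alternatives 1.6e-04 to 0.116).

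Marker lists of fibroblast classes were not called. Papillary markers (2 up, 1 down of 21, or 3 and 1 adjusted over the list alone, adjusted p = 0.956) had a mean of 0.02 against a downward camera direction. Itga8 (1.25) and Tfap2c (0.47, from 4.19 in young, a level that Y-linked genes also reached) rose and Apcdd1 fell by 0.28. Reticular and hypodermal markers (3 up, 4 down of 17, or 3 and 4 adjusted over the list alone, adjusted p = 0.667) included Fabp4 (3.02), Col14a1 (-2.69), Ppp1r14a (-1.22) and Gpx3 (-1.07). General fibroblast identity genes (3 up, 1 down of 23, or 3 and 1 adjusted over the list alone, adjusted p = 0.898) included Tbx15 (0.38), Ddr2 (0.35), Prrx1 (0.32) and Twist2 (-0.33). Single arrays left out ended the calls of Gpx3 (young 3, 0.0542 or old 4, 0.0552), Ddr2 (3 arrays, adjusted p up to 0.0626), Apcdd1 (4 arrays, up to 0.071) and Tfap2c (4 arrays, up to 0.0781).

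Senescence effectors were not called (2 up, 2 down of 19, the same counts adjusted over the list alone, adjusted p = 0.956; mean -0.03, median 0.05). Cdkn2b rose by 0.46 and Gpnmb by 0.75, Mmp3 fell by 1.09, and Glb1, the lysosomal beta-galactosidase, fell by 0.59. The cell cycle inhibitor Cdkn2a, named after its value was seen, differed by -0.08 (adjusted p = 0.561). Of 45 cell cycle genes 5 rose (4 adjusted over the list alone, adjusted p = 0.0834), including the DNA synthesis genes Mcm4 (0.62), Mcm6 (0.49), Mcm5 (0.34) and Rrm1 (0.41). The cell cycle list was called higher with the mean over all probe sets of a gene (adjusted p = 0.0153) and with the most variable one (0.0236), within a range over the alternatives to 0.684. Among clock genes 3 rose and 1 fell of 19 (3 and 1 adjusted over the list alone, adjusted p = 0.462): Usp2 (0.62), Tef (0.61), Hlf (0.56) and Npas2 (-0.37). Of 17 glucocorticoid targets Errfi1 (0.47) and Sgk1 (0.33) rose (2 adjusted over the list alone, adjusted p = 0.241). Single arrays left out ended the calls of Sgk1 (young 2, adjusted p = 0.052), Errfi1 (5 arrays, up to 0.0741), Mcm6 (5 arrays, up to 0.0591), Mcm5 (6 arrays, up to 0.109) and Tef (5 arrays, up to 0.0855). With the mean over all probe sets the calls of Mcm5 (0.19, adjusted p = 0.0801) and Tef (0.49, 0.0781) were lost too.

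Of 43 oxidative phosphorylation genes 1 rose and 2 fell by limma (0 and 1 adjusted over the list alone, 5 and 7 at an unadjusted p under 0.05). The list had adjusted p = 0.489, and adjusted p = 0.00654, lower, with the background index as a covariate (range over the alternatives to 0.972), with Sdha at 0.34, Ndufa4 at -0.49 and Sdhc at -0.18. Ribosomal protein genes had a mean of 0.08 ± 0.01 (SE, camera adjusted p = 0.00703, adjusted p = 0.592 with an estimated correlation), with Rpl19 (0.19) the 1 called gene of 40, and by limma 0 adjusted over the list alone and 12 higher at an unadjusted p under 0.05. With the background index as a covariate this list had adjusted p = 0.223 (range over the alternatives 0.00347 to 0.592). The calls of Rpl19 (adjusted p up to 0.0931) and Sdhc (up to 0.13) were lost with any array of the 8 left out, and that of Sdha without young replicate 4 (0.0567). Sdha also lost its call after median centring (0.0535) and with the mean over all probe sets (0.16, adjusted p = 0.0794).

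**Figure D2:**
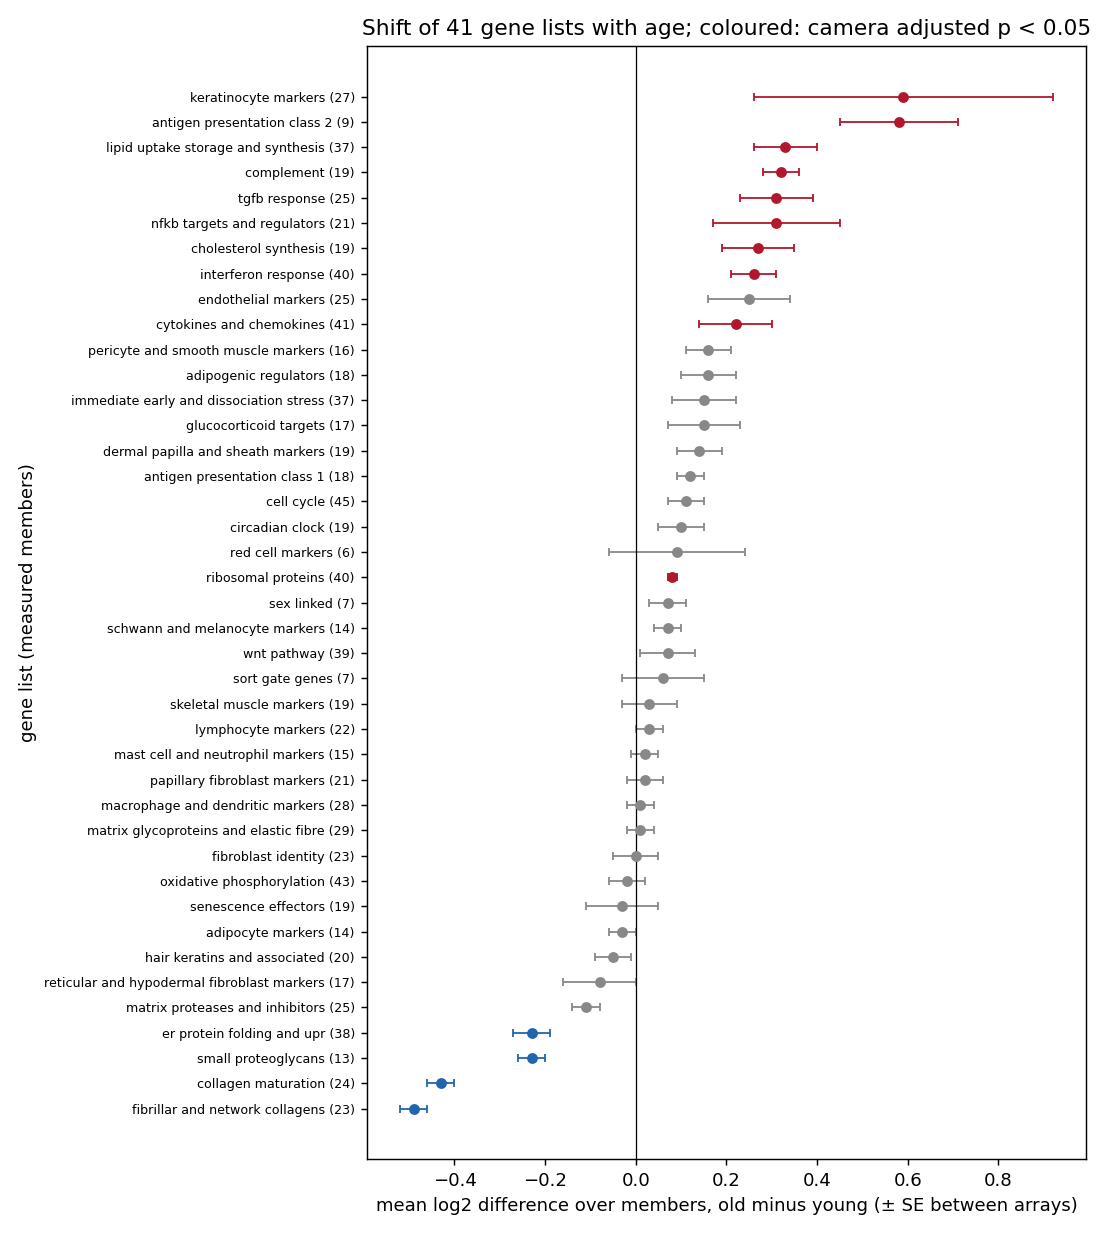
Mean log2 difference, old minus young, over the measured members of each of 41 gene lists (points, number of members in parentheses) with the SE between arrays (bars). Lists past the camera threshold are coloured, and collagens lie lowest at -0.49 and keratinocyte markers highest at 0.59 with a wide bar.

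In all, 10 lists were called higher and 4 lower by camera with the preset correlation, and 1, the collagens, with an estimated correlation. Of the 14 called lists, 11 had array scores with the exact permutation p of 0.0286, the smallest that the arrays allow. Regrouping the arrays showed that 5 of 35 splits, the real one included, called at least 14 lists, so the number of called lists alone did not set the ages apart.

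None of the 7 genes of the sort gate passed the threshold by limma without a covariate, but Cd24a lay close to it and passed under several alternatives. Pdgfra differed by 0.16 (adjusted p = 0.307) and Cd34 by -0.04 (adjusted p = 0.729). Among the excluded markers, Cd24a differed by -0.67 (adjusted p = 0.0515), Epcam by 0.34 (adjusted p = 0.0746), Pecam1 by 0.37 (adjusted p = 0.294), Ptprc by 0.17 (adjusted p = 0.101) and Kit by 0.10 (adjusted p = 0.314). The gate list as a whole had adjusted p = 0.474, with 0 of 7 called over all genes and adjusted over the list alone, and 2 higher and 1 lower at an unadjusted p under 0.05. Cd24a was called lower after median centring (-0.69, adjusted p = 0.0311), further quantile normalization (0.026), array weights (0.00859), without the dimmest 25% (0.0428) or 50% of genes (0.0376), with the most variable probe set (0.0495) and without young replicate 1 (0.0233) or old replicate 4 (0.0169), and its adjusted p ranged to 0.479 over the alternatives. With the specimen number as a block Cd24a was also called lower (limma adjusted p = 0.00643 fixed, 0.0472 random). Epcam was called higher after quantile normalization (0.0377) and with array weights (0.0449, range to 0.697), and Pecam1 without old replicate 1 (0.60, adjusted p = 0.0149, range to 0.554).

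Keratinocyte markers had a list mean of 0.59, old minus young, with overlapping array scores: old arrays scored -0.28, 0.12, 0.40 and, in replicate 4, 0.93. Of 27, 6 rose and 3 fell (9 and 3 adjusted over the list alone); Krt14 rose by 1.65 ± 0.30 (SE, adjusted p = 0.00469) and Krt5 by 1.04 ± 0.30 (SE, adjusted p = 0.0379). Pkp1 (-1.42), Trp63 (-0.41) and Lor (-0.60), named after their values were seen, fell. The list had camera adjusted p = 0.00571 and adjusted p = 0.746 with an estimated correlation, and its array scores had an exact permutation p of 0.114. The call of Krt5 was lost without any of 6 of the 8 arrays (adjusted p up to 0.0949).

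Apart from keratinocyte markers and class 2 antigen presentation genes, cell type lists were not called. Endothelial markers (5 up, 2 down of 25, the same adjusted over the list alone, adjusted p = 0.32) included Flt1 (0.61) and an Eng value of -0.02 (1 other probe set of Eng went the other way at an unadjusted p under 0.05). Eng was called higher with the mean over its probe sets (0.18, adjusted p = 0.0309) and with the most variable one (0.39, 0.0057; range over the alternatives to 0.969), while Plvap (-0.50) and Egfl7 (-0.30), named after their values were seen, fell. With the background index as a covariate the endothelial list, which holds Fabp4 and Tek (named after its value was seen), had adjusted p = 0.00501 (range over the alternatives to 0.746). Pericyte and smooth muscle markers (3 up, 1 down of 16, or 5 and 1 adjusted over the list alone, adjusted p = 0.474) included Ndufa4l2 (-1.32). Macrophage and dendritic markers (2 up, 2 down of 28, the same adjusted over the list alone, adjusted p = 0.635) included Csf1r, the colony stimulating factor receptor, at -1.92. Adipocyte markers (2 up, 1 down of 14, the same adjusted over the list alone, adjusted p = 0.969) included Trarg1 (0.52) and Aspg (-1.33). Dermal papilla and sheath markers (2 up, 1 down of 19, or 4 and 2 adjusted over the list alone, adjusted p = 0.676) included Fgf10 (1.28) and Fgf7 (0.35, adjusted p = 0.188). Schwann and melanocyte markers (2 up, 1 down of 14, the same adjusted over the list alone, adjusted p = 0.349, adjusted p = 0.0482 with the covariate, range to 0.651) included Mal (0.61, adjusted p = 0.0509 without young replicate 4) and Pmp22 (0.17, adjusted p = 0.115). Hair keratins (1 up, 1 down of 20, the same adjusted over the list alone, adjusted p = 0.181) included Tchh (0.66) and Krtap3-1 (-0.07, adjusted p = 0.613).

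In lymphocyte (adjusted p = 0.935), mast cell and neutrophil (adjusted p = 0.833), skeletal muscle (adjusted p = 0.805) and red cell lists (adjusted p = 0.764) 0 members were called by limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 lymphocyte and 1 mast cell or neutrophil marker were higher, as were 1 muscle and 1 red cell marker, and 1 muscle and 2 red cell markers were lower. Examples were Thy1 (-0.04), Cd2 (0.20), Cma1 (0.04), Mpo (0.17), Eno3 (-0.12), Tnni2 (-0.24), Hba-a2 (-0.14) and Bpgm (0.27). In young, Thy1 averaged 12.14, Hba-a2 11.31 and Bpgm 8.49, above all non-specific probe sets (up to 7.82). Below that level lay Cd2 (4.63), Cma1 (5.33), Mpo (4.20), Eno3 (6.66) and Tnni2 (5.48). Which cells gave the Thy1 and Hba-a2 signal was not tested. Tnni2 was called lower after quantile normalization (adjusted p = 0.049), with array weights (0.0377) and without young replicate 1 (0.0259), within a range over the alternatives to 0.662. Skeletal muscle and red cell means were 0.03 and 0.09 against a downward camera direction. The red cell mean rested on old replicate 2 (score 0.49), as the other old arrays scored -0.16, -0.12 and -0.03. Dissociation stress genes (5 up, 2 down of 37, or 6 and 2 adjusted over the list alone, adjusted p = 0.229) included Nr4a2 (0.93, with 2 other probe sets lower at an unadjusted p under 0.05) and Egr1 (0.04, adjusted p = 0.725), the latter at 12.90 in young. Sex-linked genes had adjusted p = 0.579 (0 called by limma, 2 higher adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05). Xist (0.19, adjusted p = 0.0521) was called higher with the mean over its probe sets (adjusted p = 0.00832) or the most variable one (0.0322), without the dimmest 50% of genes (0.0411), with trend and robust settings (0.0281) and with array weights (0.04), within a range over the alternatives to 0.499. Xist lay between 10.94 and 11.27 and 3 Y-linked genes between 3.51 and 4.39 on all arrays. That level is no general floor, since non-specific sets of 17 GC bases averaged 4.55 in young and those of 25 reached 7.82 on 1 array.

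**Figure D3:**
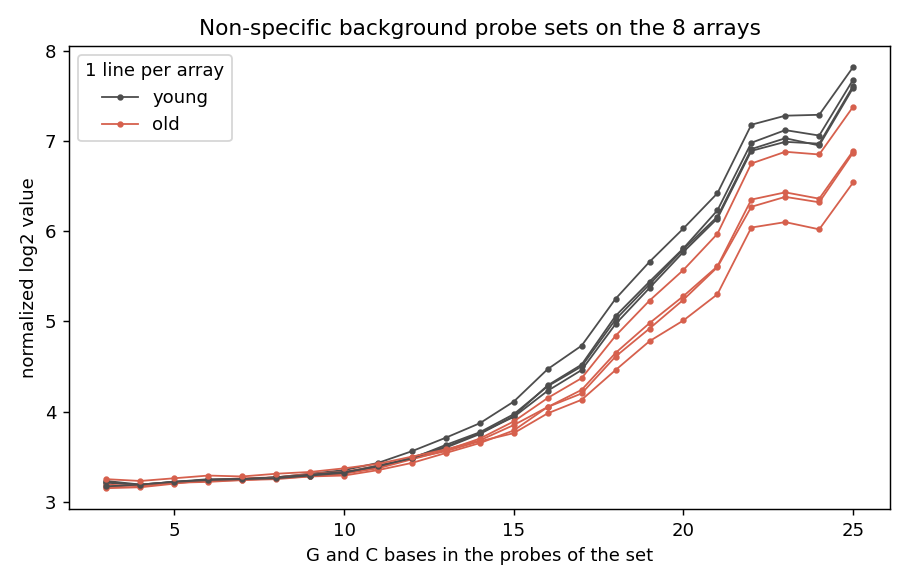
Normalized log2 values of 23 non-specific background probe sets against the number of G and C bases in their probes, 1 line per array. Lines lie close at low GC, while at 25 GC bases young arrays average 7.67 and old arrays 6.92.

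The spread between animals was not shown to differ between ages. The median gene had an SD of 0.101 among young and 0.120 among old animals, a median log2 ratio of 0.21 (exact permutation p = 0.257). Without old replicate 1 the ratio was -0.04 and without old replicate 4 it was 0.04.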

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

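The tests of cell sources and of the fibroblast share were chosen after the results were seen. Collagen and collagen maturation genes differed by -0.46 over 47 genes (interval -0.50 to -0.41). Non-specific background rich in G and C was lower in old by -0.61, but with it as a covariate the collagen difference was -0.47 (95% interval -0.57 to -0.37), which argues against it as the whole cause. A lower share of fibroblast RNA would lower 16 other fibroblast identity genes alike, yet these differed by 0.05. The collagen score fell relative to them by 0.51 with no overlap of the ages (difference -0.51, exact permutation p = 0.0286). The 16 excluded the brightest identity genes and those of the collagen and proteoglycan lists, while the collagen score had no brightness cut. Age itself and unrecorded differences in handling stay open.

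Of 27 keratinocyte markers 6 rose and 3 fell, and their array scores overlapped, with young replicate 3 (0.31) above old replicates 1 (-0.28) and 2 (0.12). Their mean within-age correlation was 0.64, above 100% of 10000 random lists matched on level (median 0.03). The estimated correlation was also high in NF-kB (0.49) and oxidative phosphorylation genes (0.40). The comparison with random lists therefore does not tell keratinocyte RNA from genes regulated together within fibroblasts. Keratinocyte RNA in the sorted cells stays a candidate source, although the sort excluded EpCam. Krt5 averaged 9.72 in young and 10.76 in old, and Krt14 averaged 8.09 and 9.75, so both had clear signal at both ages. Of the 27 markers 9, 1 of which another list also holds, lay above all non-specific probe sets (up to 7.82). The falls of Pkp1, Trp63 and Lor do not follow from such RNA. An age change of keratinocyte genes within fibroblasts was not tested.

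Fabp4 and Tek rose by 3.02 and 1.73 (Tek was named after its value was seen). The other 23 endothelial markers had a median difference of 0.05 (bootstrap interval -0.01 to 0.17), far below both rises. The 15 of them above Y-linked genes had 0.02 (-0.26 to 0.15, or 0.11 with the background covariate, -0.04 to 0.27). Most of these markers lay below the highest non-specific probe sets, so their medians do not decide whether endothelial RNA was the whole cause. The CD31 gate excludes endothelial cells. Other values go with endothelial RNA: Flt1 rose by 0.61 (limma adjusted p = 8.3e-04, or 0.227 with the covariate). Pecam1 (5.44 in old) was called higher without old replicate 1 (0.60) and Eng with other probe sets (0.18 and 0.39). With the covariate the whole list, Fabp4 and Tek included, was called higher by camera (mean 0.42, adjusted p = 0.00501). Without the covariate 5 of its 25 members rose and 2 fell. An endothelial share therefore stays open. Background depends on GC, and only 1 of the 25 endothelial markers, Eng, and 0 of the adipocyte markers lay above all non-specific probe sets (up to 7.82), so dim markers may not register such a share. The 14 adipocyte markers had a median of -0.01 (-0.06 to 0.12) and the 11 above Y-linked genes -0.03 (-0.10 to 0.19, or 0.21 with the covariate, -0.03 to 0.34). Adipoq was at 3.59 in old. As 0 of these markers lay above all non-specific probe sets, their medians do not decide whether adipocyte RNA was the whole cause. A change within fibroblasts may remain, untested.

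Of 368 groups of 4 animals looked at, 20 held an animal far from the other 3, against 18.4 by chance (1 in 20). Low were Akr1c14 in young replicate 1 (4.56), Tef in old replicate 1 (7.30) and the adipocyte marker score in old replicate 1 (-0.09). High in young were Tent5b (4.94, replicate 4), Col7a1 (8.15, replicate 3), Tbx15 (9.19, replicate 3) and, in replicate 1, Ebf2 (5.49), Twist2 (10.30), Mpo (4.24) and the lymphocyte score (0.05). High in old replicate 1 were Il18 (6.24), Glb1 (8.09), Ccn2 (8.46), Pmp22 (12.19) and Eno3 (6.70). High in old were also Mmp11 (8.77, replicate 2) and, in replicate 4, Slc6a2 (6.92), Epcam (4.99), the senescence score (0.18) and the sex-linked score (0.14). Outside the named genes, 1352 probe sets with no listed gene passed the threshold, 838 higher and 514 lower.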

How the results depend on the processing

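The background covariate and the bright-member restriction were chosen after seeing the data. Counts of genes were 1688 higher and 1310 lower; they stayed within 1.5 times except at a fold of at least 1.5 (513 and 394) and with the background index as a covariate (68 and 99). That index correlated with age (-0.86), so standard errors rose by a median factor of 1.98, while 99.5% of called genes kept their sign. Of the 2998 called differences, 769 shrank and 183 grew by over 1.5 times, so calls ended through lost precision and, for part of the genes, smaller differences. Leaving out 1 array gave 1215 to 1709 higher and 983 to 1219 lower genes. Of 35 splits of the arrays only the real one, 1 split, gave as many genes (2998, highest other 2). This argues against chance for the gene count, but it is the smallest share that the splits allow. It does not tell age from the background index, which moved with age. For lists, 5 splits gave 14 or more (highest 18), so chance is not excluded, and the other 4 exchanged 1 animal per age. Lists called higher fell from 10 to 3 without the dimmest 50% of genes (29 of 41 lists had enough members left, and 13 of the 14 called, class 2 antigen presentation not among them; 6 were lost), to 0 with an estimated correlation and to 6 with fry; those lower fell from 4 to 1 with an estimated correlation. The cause of these losses was not tested. The small proteoglycans had an estimated correlation of -0.04, below the preset 0.01, so a higher correlation did not end that call. Calls ended for lipid genes, cholesterol synthesis, cytokines, TGF-beta, ribosomal and keratinocyte genes without the dimmest genes, for cholesterol synthesis, cytokines, NF-kB and keratinocyte genes with fry, for ribosomal genes with a random block, for keratinocyte genes with trend and robust settings, and for lipid genes with bright members alone (adjusted p = 0.0876). Calls were gained for cell cycle genes with other probe set choices, for proteases with a random block (0.0369), trend and robust settings and fry, and for oxidative phosphorylation, endothelial and Schwann genes with the covariate. The covariate also ended the calls of lipid (camera adjusted p = 0.0656), cholesterol synthesis (0.12), NF-kB (0.0656) and ribosomal genes (0.223). Leaving out any 1 array left 10 and 4. The spread ratio ran from -0.04 to 0.41. The specimen number as a replicate block gave 1838 higher and 1268 lower genes (random block 1743 and 1342), and Cd24a was called lower (0.00643; random 0.0472) and Xist higher (random 0.0495), while the fixed block ended 6 named calls, of Ebf2 (0.0587), Ppargc1b (0.071), Nfkbiz (0.0677), Mcm5 (0.0713), Sdhc (0.118) and Rpl19 (0.103), and the random block 0 of 122; deviations of equal numbers correlated at 0.29, 0.05, -0.04 and 0.22, and 2 of 4 young arrays were closest to the old array of their number, so the numbers were not taken as pairs. Eng turned from -0.02 to 0.18 over all probe sets and 0.39 with the most variable set. Of 122 called named genes, 98 kept their call with each array left out. Of the alternatives run for single genes, 96 kept it under all but the covariate, and 26 under all. Other thresholds and the test of all probe sets were run for counts only. Genes left out as dim were not counted as lost, and without the dimmest 50% of genes 103 of the 122 were compared. Calls of Apcdd1, Clu, Ddr2, Ebf2, Elovl6, Errfi1, Flrt1, Gpx3, Klf5, Krt5, Mal, Mcm5, Mcm6, Nfkbiz, Pdia3, Ppargc1b, Rpl19, Sdha, Sdhc, Sgk1, Tef, Tfap2c, Tnfaip3 and Zfp521 were lost without at least 1 array. Values near background, which rises with GC, may understate differences. As GC-rich background was itself lower in old (-0.61), they may also overstate falls. Among called named genes, Col4a5 in old and Il15, Ppargc1b, Tfap2c, Tcf24, Tent5b and Tchh in young lay at levels that Y-linked genes also reached.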

Other observations

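Both gene lists here were drawn up after the largest changes were seen, their camera tests were set out before the results, and the alternatives and array score tests were added after them. Beyond Aldh1l2 and Bcat1, other genes of the amino acid response were examined. Of 35 genes of the amino acid response, holding none whose values had been looked at, 13 fell and 1 rose. Aldh18a1, of proline synthesis, differed by -1.04 ± 0.09 (SE), asparagine synthetase Asns by -0.84 ± 0.19 (SE) and Phgdh, the first enzyme of serine synthesis, by -0.59 ± 0.09 (SE). The tRNA synthetases Gars (-0.70) and Aars (-0.57) and the translation repressor Eif4ebp1 (-0.70) fell, whereas the glutamine transporter Slc1a5 rose by 0.83. The list had a camera p of 1.3e-04 (adjusted p = 2.6e-04 over the 2 lists), but adjusted p = 0.127 with an estimated correlation and a bootstrap interval of the median from -0.35 to 0.00. All 4 old array scores lay below the young ones (exact permutation p = 0.0286, the smallest the arrays allow). With the background index as a covariate the mean was -0.26 against -0.21 without it (adjusted p = 6.8e-05), and over 21 alternatives, run after seeing the data, the adjusted p ranged from 6.8e-05 to 0.127. A lower amino acid response in old fibroblasts may be a hypothesis; its check would be the same list in other animals, which was not tested.

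Whether imprinted genes shift as a group was asked because of 4 single genes. Mirg fell by 2.71, and Meg3 (-1.64) and Rian (-1.58) of the same cluster, named after their values were seen, fell as well, while Igf2 rose by 2.37. In 19 other imprinted genes, 2 rose and 2 fell, with Peg3 at -1.40 ± 0.08 (SE) and Zdbf2 at 0.61 ± 0.12 (SE). Their camera p was 0.165, the adjusted p over the 2 lists ranged from 0.0473 with fry to 0.678 with the covariate over 21 alternatives, their array scores had an exact permutation p of 0.0857, and the bootstrap interval of the median ran from -0.20 to 0.02. This leaves open whether imprinted genes shift one way: members moved in both directions, so the bound set out beforehand, an interval of the median within 0.2 of 0, which this interval touches, was taken not to decide it, a judgement made after the values were seen.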
